A study of Caenorhabditis elegans with 4 samples.

How the data were processed

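The study measured SDC-1 occupancy by ChIP-seq in C. elegans N2 mixed-stage embryos, with 2 ChIP samples and 2 input DNA samples. Per the labels' protocols, embryos were crosslinked with formaldehyde, chromatin was sonicated, and single-end indexed adaptors were ligated to the recovered DNA. The submitters' processing notes name BWA and the genome build ce10, and the file headers name WormBase WS220. The role and version of BWA, the input used as control and any filtering of reads or peaks are not given in the sources used here.

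The files are peak lists in GFF3 with a start, an end and a score per peak. Per the files' source column, the replicate lists were called with MACS on each ChIP sample, and the whole-series list with MACS v2. How the replicates were combined for the whole-series list is not given in the sources used here. The score of each peak is the authors' own value, as deposited, and its definition is not given in the files. Replicate scores started at 50.3 and 50.08, and whole-series scores at 1.31, so the lists use different scales. Levels of scores were therefore compared only within a list, and scores of matched peaks across lists only by correlation (Spearman's rho, and Pearson's r of log10 scores). Many replicate scores tie at 3100 (18 peaks in replicate 1, where 1 peak lies above it at 3119.7, and 44 in replicate 2, where it is the largest) and the largest whole-series scores tie at 170.28 (14 peaks), so ranks among the strongest peaks are limited. Median peak width was 266 bp in the whole-series list, 497.5 bp in replicate 1 and 552.5 bp in replicate 2. The lists covered 488, 441 and 909 kb in that order. Read depth is unknown. The number of peaks sets the precision of counting only, and the experiment has 2 ChIP samples.

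Peaks were analysed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The length of each chromosome was taken as the highest position reached by a peak in any of the 3 lists, because a WS220 sequence or annotation was not used here. This is a lower bound on the true length. By it, X spanned 17.7 Mb and the autosomes 82.2 Mb. A gene table of another assembly, WBcel235, was not used for positions, since coordinates of different builds cannot be mixed. The planned tests of peaks near gene starts, of fixed gene lists and of an X-enriched sequence motif were therefore not run.

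The main tests, gene lists, alternatives and the rule for named peaks were fixed before the data were examined. The rule without an annotation was the 10 highest-scoring peaks on X and the 10 highest-scoring on the autosomes of the whole-series list, ties by coordinate. Peaks counted as shared when they overlapped by at least 1 bp. Overlap between replicates was tested against 10000 circular shifts of the replicate 1 peaks within each chromosome. The share of peaks on X was tested with an exact binomial test against length. Scores on X and autosomes were compared with a permutation test of the difference in medians (100000 resamples). The top 25% by score was compared with the rest by Fisher's exact test. Counts among autosomes were tested with a Monte Carlo approximation of the exact multinomial test (100000 draws). Its draws were ranked by chi-square against length, not by their probability. The threshold was 0.05 throughout. Each of these asked a different question and was read without adjustment, while families of correlations, widths and bins were adjusted by Benjamini-Hochberg. The plan did not include the tests of recurrence on X against autosomes, of the replicate difference in X share or of the lowest score quartile. Those were also read without adjustment. Nor did the plan include the families of correlations, widths and bins. For counts over bins, the draws of the same approximation were ranked by variance over mean. The alternatives were each replicate list alone, peaks found in both replicate lists, the 50% of peaks with the highest score, merging of peaks less than 1000 bp apart, counting covered bases, stricter definitions of overlap, the top 10% by score and the middle 50% of the autosomes. After the data were seen, 2 more were added: peaks found in at least one replicate list, and peaks outside replicate regions wider than 2000 bp.

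The tests of the X share and of overlap were tested on simulated data first, in lists of 530 peaks placed at random with the widths of replicate 1. The test of counts over bins was tried on random positions along X instead, and the other tests were not simulated. Without an effect, 7% of 200 simulated lists passed the test of the X share and 2.5% passed the overlap test. Of 200 simulated sets of positions, 5.5% passed the test of counts over bins. With a 2-fold X density, shared peaks planted, or a crowded bin planted, 100% passed the corresponding test. Peaks in real lists cluster more than simulated ones, so the binomial p-values can be too small.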

Results

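Binding of SDC-1 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mixed-stage wild-type embryos of the C. elegans strain N2. SDC-1 is a subunit of the dosage compensation complex, which binds the X chromosomes of hermaphrodites and lowers their transcription. The embryos came from a population of both sexes, and the antibody was an affinity-purified rabbit polyclonal raised against SDC-1. There were 2 ChIP samples and 2 input DNA samples. The data analysed here are 3 lists of peaks called by the authors, with 530 peaks for ChIP replicate 1, 1160 for replicate 2 and 1352 in a list for the whole series. Input libraries were not analysed here. The files give no read totals, so the sequencing depth behind each list is unknown. Nothing in the labels says whether the replicates came from separate embryo collections, so agreement between them may be technical. Intervals below are exact Clopper-Pearson 95% intervals. They treat peaks as independent and cover counting error only.

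The first comparison asked how many peaks recurred between the replicates. Of the 530 replicate 1 peaks, 456 (86%, interval 82.8 to 88.9%) overlapped a replicate 2 peak by at least 1 bp. Of the 1160 replicate 2 peaks, 422 (36.4%, interval 33.6 to 39.2%) overlapped a replicate 1 peak. Replicate 1 peaks shifted around each chromosome overlapped replicate 2 peaks 10.2 times on average and at most 79 times. The observed overlap was larger than in all 10000 shifts (one-sided circular-shift permutation test, p = 1.0e-04, the smallest these shifts can give). On X, 155 of 169 replicate 1 peaks recurred (91.7%), against 301 of 361 on the autosomes (83.4%), a difference past the threshold (two-sided Fisher's exact test, p = 0.0103). In replicate 2 the corresponding shares were 47.4% of 306 X peaks and 32.4% of 854 autosomal peaks (p = 4.5e-06, same Fisher's exact test). The authors' scores of matched peaks ranked more alike on X than on the autosomes. Spearman's rho across peaks was 0.86 over 155 X peaks and 0.57 over 301 autosomal peaks, with Pearson's r of log10 scores at 0.84 and 0.58 (permutation p = 1.0e-04 for each rho, adjusted p = 1.2e-04 over 6 correlations). The difference between these correlations was not tested, and peaks of one list are not independent replicates.

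The whole-series list was then compared with the replicate lists by overlap. Of its 1352 peaks, 499 (36.9%) overlapped a peak in both replicate lists, 435 (32.2%) a replicate 2 peak alone, 24 (1.78%) a replicate 1 peak alone and 394 (29.1%) no replicate peak. Peaks found in both replicates had a median score of 18.2, and those found in neither had a median score of 4.44. In the 25% of whole-series peaks with the highest score, 76.9% were in both replicate lists and 0.296% were in neither. In the 25% with the lowest score, 20.4% were in both and 46.7% were in neither.

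The main comparison asked whether SDC-1 peaks lay on X more often than chromosome length predicts. The X chromosome held 388 of the 1352 whole-series peaks (28.7%, interval 26.3 to 31.2%), while it makes up 17.7% of the chromosome length spanned by the peaks. Peak density was 21.9 peaks per Mb on X and 11.7 per Mb over the 5 autosomes, a ratio of 1.87 (interval 1.66 to 2.11; exact binomial test, two-sided, p = 3.3e-23). Both replicates showed the same direction. X held 31.9% of replicate 1 peaks (169 of 530, p = 2.6e-15, exact binomial test) and 26.4% of replicate 2 peaks (306 of 1160, p = 2.0e-13, exact binomial test). Across the replicates the density ratio was 1.92 ± 0.36 (SD, n = 2), and the share of X was 29.1% ± 3.89 (SD, n = 2). The replicate shares lay 5.51 percentage points apart. Fisher's exact test (two-sided) gave p = 0.0229, but it treats the lists as independent, and most replicate 1 peaks overlapped replicate 2 peaks, so this p is only a rough guide. By covered bases, X peaks took 9.66 bp per kb of chromosome and autosomal peaks 3.85 bp per kb in the whole-series list, with 6.86 against 3.89 in replicate 1 and 13.3 against 8.19 in replicate 2.

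**Figure D1:**
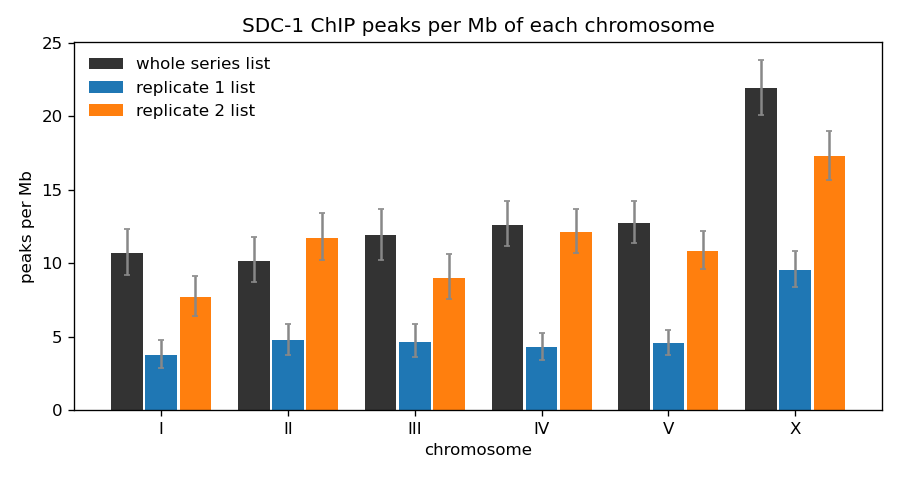
Bars give SDC-1 peaks per Mb (y axis) on each chromosome (x axis) for the whole-series list and the 2 replicate lists; error bars are exact 95% binomial intervals of each chromosome's share of its list. X stands above every autosome in all 3 lists, at 21.9, 9.55 and 17.3 peaks per Mb.

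The excess on X was greatest among the strongest peaks. X held 154 of the 338 peaks in the top 25% by score (45.6%, interval 40.2 to 51%) and 234 of the other 1014 (23.1%, interval 20.5 to 25.8%; Fisher's exact test, two-sided, p = 1.8e-14). In the top 10%, 80 of 135 peaks were on X (59.3%, interval 50.5 to 67.6%). In the 25% with the lowest scores, 64 of 338 peaks were on X (18.9%, interval 14.9 to 23.5%), and this share was not distinguished from the 17.7% given by length (exact binomial test, two-sided, p = 0.569). The density ratio of X to autosomes was 3.89 in the highest score quartile, 1.49 in the next, 1.64 in the one after and 1.09 in the lowest. The top 25% of each replicate list also lay on X more often than the rest, with 47.7% against 26.6% in replicate 1 (p = 1.4e-05) and 39.7% against 22% in replicate 2 (p = 9.4e-09, both Fisher's exact test, two-sided).

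The median whole-series score was 10.2 on X and 6.17 on the autosomes (difference 4.07; two-sided permutation test, p = 1.0e-05, the smallest 100000 resamples can give). Replicate 1 scores, on another scale, had medians of 241 on X and 141 on the autosomes, and replicate 2 scores had medians of 187 and 117 (p = 1.0e-05 for each, same permutation test). The size of the whole-series difference depended on which peaks were kept. It was 40.3 among the 499 peaks found in both replicates and 17.1 among the 50% of peaks with the highest score. The latter set was chosen by the score being compared, so its larger difference is not separate support.

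**Figure D2:**
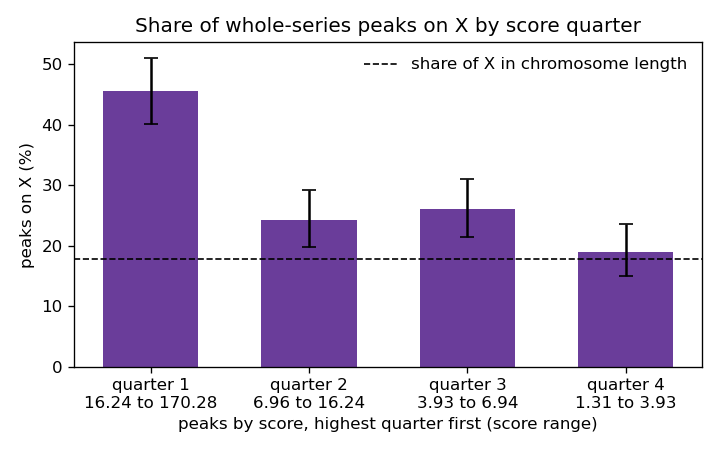
Bars give the percent of whole-series peaks on X (y axis) in each quartile of the list by score (x axis, highest first, with score ranges); error bars are exact 95% binomial intervals and the dashed line is the 17.7% share of X in chromosome length. The highest quartile stands at 45.6%, and the interval of the lowest quartile, at 18.9%, includes the dashed line.

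The 34 highest-scoring whole-series peaks all lay on X, and 14 of them tied at the largest score of 170.28. Taken by position (WS220 coordinates), the first 10 of these were X 784894 to 786077, 805907 to 807386, 1344106 to 1346134, 1626598 to 1627710, 1888230 to 1889097, 2996114 to 2997716, 8035810 to 8037216, 9465268 to 9466277, 11936649 to 11937917 and 13700048 to 13701592. Their widths ran from 868 to 2029 bp. Each overlapped a peak in both replicate lists. In replicate 2 every one of the 10 had a score of 3100, a value shared by 44 peaks of that list. In replicate 1 the peaks at 784894 and 1344106 scored 2304 and 2999, the peak at 1888230 scored 3119.7, and the other 7 scored 3100. Because the scores tie at these limits, the order among the strongest X peaks is not resolved. The genes at these positions are not named, since a WS220 annotation was not used here.

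The strongest autosomal peak, on II from 12550852 to 12551386, had a whole-series score of 127.42 and ranked 35 in the list. The next were II 7200018 to 7200552 with a score of 98.1, III 5031244 to 5031853 with 95.7, I 13463776 to 13464252 with 92.8, V 12303377 to 12303824 with 92.8 and IV 8926988 to 8927626 with 92.2. The remaining 4 of the 10 were III 10989357 to 10989999 with a score of 91.3, III 4369280 to 4369850 with 90.9, II 5104911 to 5105484 with 88.8 and IV 8375255 to 8375732 with 87.9. Their widths ran from 448 to 643 bp, and all 10 overlapped peaks in both replicate lists. Their replicate 1 scores ran from 329 to 950 and their replicate 2 scores from 998 to 1987, below the 3100 reached by the 10 X peaks in replicate 2. That contrast holds for peaks picked by whole-series score, since other autosomal peaks did reach 3100 in replicate 2. Among them were regions on III from 7444258 to 7448839 and on V from 4333155 to 4336751. Their highest whole-series scores were 9.04 and 19.81.

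**Figure D3:**
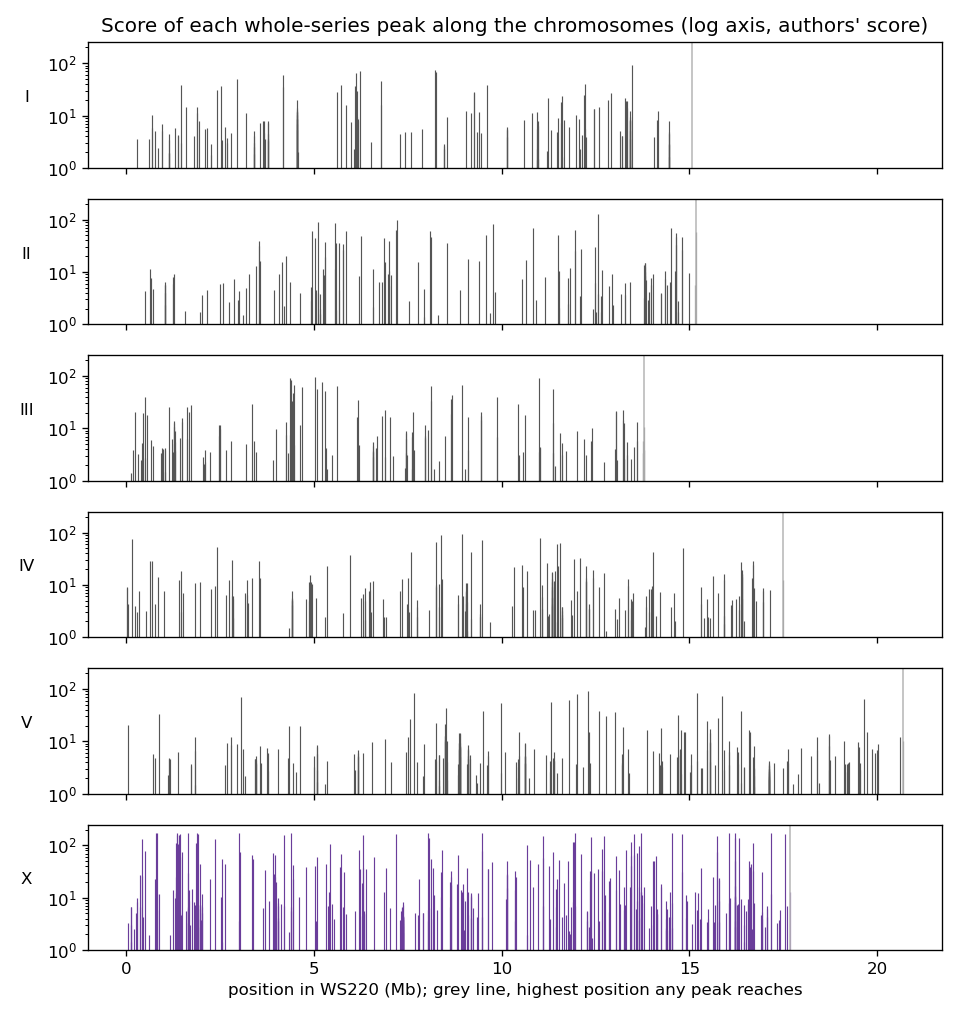
Each vertical line is a whole-series peak at its WS220 position in Mb (x axis), with its height the authors' score on a log axis (y axis); each panel is a chromosome, X in purple, and a grey line marks the highest position reached by any peak. Scores above 127.42 occur on X alone, up to 170.28, and peaks with scores under 10 occur on every chromosome.

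Among the autosomes, the whole-series counts did not depart from chromosome length past the threshold. Chromosomes I, II, III, IV and V held 161, 154, 164, 221 and 264 peaks, against 177, 178, 162, 205 and 243 given by length (chi-square 7.73, Monte Carlo approximation of the exact multinomial test, p = 0.101). Replicate 1 gave a chi-square of 2.35 (p = 0.671). Replicate 2 departed from length (chi-square 21.2, p = 3.3e-04, same approximation of the exact test), with 116 peaks on I where length gives 157 and 212 on IV where length gives 182. The whole-series test also passed the threshold when peaks inside replicate regions wider than 2000 bp were left out (chi-square 12.0, p = 0.0177).

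The autosomes of C. elegans have gene-rich centres and repeat-rich arms, and peaks were compared between these parts. The middle 33.3% of each autosome together held 322 of 964 autosomal whole-series peaks (33.4%, interval 30.4 to 36.5%), a share not distinguished from 33.3% (exact binomial test, two-sided, p = 0.973). The share was 36.8% in replicate 1 (interval 31.9 to 42%) and 30.3% in replicate 2 (interval 27.3 to 33.5%), and neither passed the threshold (exact binomial p = 0.163 and 0.0641).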

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

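Of 39 alternative settings over 6 results, 34 kept the direction and the side of the threshold. Counts among autosomes have no direction, so for them only the side of the threshold was compared. The 34 included the overlap of replicates, the score difference and the share of X in the top 25% under every setting run. They also included the share of peaks on X under all but 1. Counting covered bases moved the share on X from 28.7% to 35.0%, outside its interval, in the whole-series list, and lowered it in the replicate lists, from 31.9% to 27.5% (also outside its interval) and from 26.4% to 25.95%. The whole-series score difference of 4.07 became 12.4 among peaks in at least one replicate list, 17.1 among the 50% with the highest score and 40.3 among those in both. The 50% setting selects on the score being compared, which also defines the top 25%, so for neither result is it separate support. Counts among autosomes passed the threshold in replicate 2 and not in replicate 1 (chi-square range 2.35 to 21.2 over the replicate lists), and with wide replicate regions left out, a setting added after the data were seen (chi-square 12.0); the cause was not tested. The share in the middle 33.3% of the autosomes, not distinguished from length, was below that value in replicate 2 (30.3%, with 36.8% in replicate 1), and the share in the middle 50% was 48.3%, below 50%; none of these passed the threshold. In replicate 2 alone the middle 50% held 46.5% (exact binomial p = 0.0434), which did. Over the planned settings, the overlap of replicate 1 peaks ranged from 66.6% (at least 50% of both widths) to 91.7% (X alone), and it was 97.0% for the top 25% of replicate 1 by score. Tests of gene starts, gene lists and the X motif were not run. No paired analysis was possible because the input libraries were not analysed here and all peaks come from one group. The limiting factors are the unknown read depth, tied top scores and 2 replicates.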

Other observations

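The tests of score agreement between replicates on autosomes, of chromosome centres by score, of widths on X against autosomes and of the narrow and wide subsets with replicate 1 were chosen after the data were seen. Within X, SDC-1 peaks were crowded near the left end. The stretch from 0.983 to 1.97 Mb held 47 whole-series peaks, against a mean of 21.6 over 18 equal bins of about 1 Mb, and it was also the fullest bin in replicate 1 (24 peaks, mean 9.39) and replicate 2 (34 peaks, mean 17). The stretch from 15.7 to 16.7 Mb came next in each list, with 38, 17 and 31 peaks. After merging peaks less than 5000 bp apart the first stretch was still the fullest of X in each list (27, 17 and 25), while the second kept its place in the whole-series list alone (24). Among autosomes, the fullest bin of the whole-series list was IV from 11.3 to 12.3 Mb, with 33 peaks against a mean of 13, and it was the fullest of IV in both replicate lists, with 12 and 28 peaks. After the same merging it held 16 in the whole-series list and 17 in replicate 2, fewer than the 17 and 21 in the bin that starts at 15.4 Mb, and in replicate 1 it held 10 and was still the fullest. The crowding on IV then did not pass the threshold in any list (adjusted p = 0.247, 0.521 and 0.295 for the whole series, replicate 1 and replicate 2, Monte Carlo approximation of the exact multinomial test).

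The top 25% of autosomal peaks by score favoured chromosome centres in the whole-series list. In the 25% of autosomal peaks with the highest score, 100 of 241 lay in the middle 33.3% (41.5%, interval 35.2 to 48%), against 30.7% of the other 723 (Fisher's exact test, two-sided, p = 0.0027, adjusted p = 0.0040 over 3 lists). Replicate 2 showed the same direction, with 43% against 26.1% (adjusted Fisher's exact p = 1.5e-05), and in replicate 1 the shares were 37.8% and 36.5% (adjusted Fisher's exact p = 0.900). Across whole-series peaks, the median width was 305 bp on X and 251.5 bp on the autosomes (permutation p = 2.0e-05, adjusted p = 1.2e-04 over 6 comparisons). Over all peaks that difference did not pass the threshold in replicate 1 (506 against 492 bp) or replicate 2 (560.5 against 545 bp; adjusted permutation p = 0.698 for both). In the top 25% of replicate 1, X peaks were narrower, at 737 against 1250 bp (adjusted permutation p = 6.3e-04). In the top 25% of the whole-series list they were wider, at 443.5 against 391.5 bp (adjusted permutation p = 0.0017), and in that of replicate 2 the widths were 813 and 795 bp (adjusted permutation p = 0.850).

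The crowding on X exceeded uniform placement in the whole-series list (variance over mean 4.29, Monte Carlo approximation of the exact multinomial test, p = 1.0e-05, the smallest these draws can give, adjusted p = 6.0e-05 over 18 chromosome and list pairs). Every autosome of that list exceeded it too, so crowding of the peaks as called was not particular to X. Variance over mean ran from 1.78 on I (adjusted p = 0.0466) to 4.13 on IV (adjusted p = 6.0e-05, same approximation of the exact test). After merging X peaks less than 5000 bp apart, the variance over mean on X was 2.06 (p = 0.0061, same approximation of the exact test). The prediction written beforehand asked only for a p under 0.05 and left out the adjustment over 18 pairs that the bins need; with it the p was 0.0667. One broad region called as several peaks therefore stays open as the cause, whole or partial. Crowding by one replicate library is argued against for the peaks as called, since the larger of the 2 replicate p-values was 8.0e-05 (same approximation of the exact test). The merged replicate lists do not decide this, with p = 0.0548 in replicate 1 and 0.0074 in replicate 2 by that approximation of the exact test (adjusted p = 0.247 and 0.0667). No biological explanation was tested.

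Replicate 2 had 2.19 times as many peaks as replicate 1. The 738 replicate 2 peaks with no replicate 1 peak were weak, with a median score of 90.8 against 498 for the 422 shared ones (difference -407, permutation p = 1.0e-05). The prediction for replicate 2 also calling the weak sites was thus met. Background peaks or a difference in read depth would also give low scores, so this test does not tell them apart. Background spread by chromosome length as the source of all extra peaks predicts 17.7% on X. The share was 21.8% (interval 18.9 to 25%), above that if peaks are independent. Replicate 2 peaks on X were crowded, however (variance over mean 2.85 over bins), so the interval can be too narrow. The margin is small, and background alone is not excluded. A mixture of weak sites and background stays open, as does a difference in read depth, which the lists do not give.

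Whole-series and replicate scores ranked autosomal peaks differently. Spearman's rho across autosomal peaks was 0.18 with replicate 2 (660 peaks, adjusted permutation p = 1.2e-04). With replicate 1 it was -0.11 (365 peaks, adjusted permutation p = 0.0339), while on X it was 0.57 and 0.65. Whole-series peaks inside one replicate region shared its score but were permuted as independent. The autosomal ones overlapped only 524 replicate 2 peaks and 284 replicate 1 peaks. These p-values can therefore be too small, and the random subsets below, drawn peak by peak, share that limit. Among the 439 autosomal peaks inside a replicate 2 peak of at most 1000 bp, rho was 0.64, above the 95th percentile of random subsets (0.22), and among the other 221 it was 0.19. With replicate 1 the narrow subset gave 0.58 and the wide one -0.28. Unreliable replicate 2 scores are argued against by a rho of 0.57 between the replicates over 301 matched autosomal peaks. Both replicate lists came from MACS, so a bias that they share is not excluded by this agreement. The whole-series list came from MACS v2, and the effect of the caller on the ranking was not tested. A candidate explanation is that wide replicate regions hold several low-scoring whole-series peaks. The 63 replicate 2 regions wider than 2000 bp held 166 whole-series peaks with a median score of 5.25, against 6.95 over the whole list. In a picked example, the region on V from 17119893 to 17126712 scored 2404 in replicate 2 and 2932 in replicate 1. It held 6 whole-series peaks with a highest score of 2.96. Not every wide region was like this. The region on X from 805405 to 807475 held a peak scoring 170.28, and that on II from 11214162 to 11216432 held no whole-series peak.

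There were 32 replicate 2 peaks that overlapped replicate 1 peaks and no whole-series peak. Their median score was 96.1, against 546 for the 390 that did overlap one (permutation p = 0.0016), and their median width was 529.5 against 710 bp (permutation p = 0.0397). Of the predictions written beforehand, a lower score was met and a greater width was not. They included a region of 11152 bp at the right end of I, from 15060210 to 15071361, and peaks starting at position 1 of I, II, V and X. Within 10 bp of a chromosome's first position there began 5 peaks in replicate 1, 4 in replicate 2 and 0 in the whole-series list.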
